A study of Drosophila melanogaster with 10 samples.

How the data were processed

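Expression was measured in 10 samples of early L3 eye-antenna discs, 2 biological replicates for each of 5 genotypes, per the labels and the design text of the series. Per the labels' protocols, eggs were laid over 2 to 3 h, larvae grew to 96 h after egg laying, 20 to 30 discs were pooled per sample, and 50 ng of total RNA was amplified with an Affymetrix kit that starts from the poly(A) end of transcripts and hybridised to Affymetrix expression arrays in 1 colour. The deposited values are on the log2 scale, 1 value per probe set and array. Per the submitters' processing notes, they name Affymetrix Expression Console, RMA and Transcriptome Analysis Console 3.0.0.466, without the role of each. RMA corrects the background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of a probe set, so a change shared by most genes would be removed. The columns ran from 2.58 to 14.84 and their medians from 5.15 to 5.21. No detection calls, scan dates or genome build were given in the sources used here, so background could be judged only by a floor, batches could not be tested, and no coordinates are given. How the probes lie relative to the hairpin and the transgenes was not used here.

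The table held 18952 probe sets, of which 183 were controls and were left out. In the platform annotation, which is dated and can be old, 13646 of the other 18769 probe sets had 1 gene symbol, 402 had several and 4721 had none. Of the single-gene probe sets, 13543 had a gene identifier found in the gene table of the Release 6 plus ISO1 MT assembly, and 0 symbols had to be replaced. Only single-gene probe sets were used, for 11981 genes, each represented by its probe set with the highest mean over all 10 arrays. A gene was tested if at least 2 arrays lay above the floor, the 40th percentile of all values (4.66 log2 units), which kept 8702 genes and removed 3279. Of 624 genes with at least 2 probe sets, 0 to 2 per comparison had calls in opposite directions. A group mean at or under the floor is stated where a gene is named, and its fold change is then less certain. The 2301 probe sets without a single gene that passed the filter were tested in a fit of their own, and 48, 32, 139, 39, 11, 80 and 83 of them were called in the order COX7a RNAi, Delta and Notch intra against GFP, COX7a RNAi in the Delta background, interaction, Delta with COX7a RNAi against GFP, and Notch intra against Delta.

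Groups were taken from the genotypes in the labels. The main test was limma 3.58.1 in R 4.3.3 with 1 mean per genotype over all 10 arrays (5 residual degrees of freedom), contrasts for the 7 comparisons and eBayes with an intensity trend. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over the 8702 genes. The median residual SD was 0.0798 log2 units and the prior had 3.31 degrees of freedom. With 2 arrays against 2, the p-values lean on the spread pooled over all genotypes. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 217 tests (31 lists with at least 3 measured genes in 7 comparisons). A 32nd list, of dosage compensation RNAs, had no single-gene probe set and was not analysed here. With an estimated correlation, none of the 217 tests passed (lowest adjusted p = 0.634), and 11 had an unadjusted p under 0.05. The fry test, which asks whether a list's genes move one way and does not compare them with other genes, kept 3, 0, 3, 4, 0, 6 and 3 of the 8, 3, 9, 9, 3, 11 and 9 calls in the order given above. Overlaps were tested with Fisher's exact test, or simulated where 2 comparisons share the GFP arrays.

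The lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the genes the transgenes target or encode with the marker genes white, tio and tsh, the 10 highest and 10 lowest fold changes among called genes whose arrays did not overlap between the groups (for the interaction, among called genes), and up to 3 called genes with the largest change from each list, or 1 as a value where none was called. Rankings were shortened only from their end. The fit was tested on simulated data with the real means and spreads and 200 genes changed. For COX7a RNAi against GFP over 8702 genes it recovered 13 of 50 genes changed 1.25-fold, 35 of 50 at 1.5-fold, 46 of 50 at 2-fold and 48 of 50 at 4-fold, with 8 calls among 8502 unchanged genes. For the interaction it recovered 4, 22, 41 and 48 of 50, with 4 calls among unchanged genes. The alternatives tried were no filter and a filter at the 60th percentile, eBayes without a trend and in its robust form, the replicate number as a block, a fit on the compared groups alone, an ordinary linear model, 2 other scalings, all probe sets or their mean per gene, a fold change of at least 1.5, array weights, each array left out in turn, and camera with an estimated correlation and fry for the lists. Called lists and their values stand with each comparison. Those never called, with their measured genes and lowest camera adjusted p over the 7 comparisons, were cytochrome c oxidase (complex IV) subunits (9 genes, 0.0661), Notch pathway components (13 genes, 0.081), retinal determination (11 genes, 0.147), hypoxia response (7 genes, 0.0993), ecdysone response and larval timing (12 genes, 0.061), JAK/STAT signalling (7 genes, 0.257), fat body markers (4 genes, 0.378), hemocyte markers (9 genes, 0.305), neuron and glia markers (9 genes, 0.186), salivary gland markers (4 genes, 0.0764), gut markers (6 genes, 0.186), cuticle and mouth hook markers (6 genes, 0.431).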

Results

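Gene expression was profiled in eye-antenna imaginal discs of Drosophila melanogaster larvae, the larval epithelia that give rise to the adult eye, antenna and much of the head capsule. Discs were taken 96 h after egg laying, early in the last larval stage. The eyeless driver ey-Gal4 expressed UAS transgenes in the disc in 5 genotypes with 2 biological replicates each, 10 arrays in all. The control expressed GFP. The others expressed a hairpin against COX7a (COX7a RNAi), the Notch ligand Delta together with GFP (Delta), Delta together with the COX7a hairpin (Delta with COX7a RNAi), or an intracellular form of the Notch receptor (Notch intra). COX7a encodes a subunit of cytochrome c oxidase, complex IV of the respiratory chain, and carries the symbol COX7A in the probe annotation used here. The series title sets loss of COX7a beside gain of Notch function, so the comparisons ask what each does alone and whether loss of COX7a acts differently when Delta is overexpressed.

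Of the genes named by the probe annotation, 8702 were tested. Of the 11981 genes before the filter, between 8308 and 8491 lay above the intensity floor of 4.66 log2 units on each array. Replicates of a genotype correlated at Pearson's r of 0.995 to 0.997 across genes, against 0.981 to 0.996 for arrays of different genotypes. The first principal component held 41.9% of the variance and separated the Notch intra arrays (25.95 and 28.18) from the rest (-12.38 to -0.66). The second held 17.7% and separated the 4 arrays with COX7a RNAi (7.24 to 11.22) from the GFP and Delta arrays (-13.78 to -6.86), with Notch intra between them (1.98 and 4.31). The number of arrays limits the precision. Values below are log2 fold changes ± standard error from limma with 2 arrays per genotype, and calls are at a Benjamini-Hochberg adjusted p under 0.05.

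The targeted genes followed the labels. COX7A stood at 13.41 and 13.32 log2 units in the GFP arrays, at 13.21 and 13.29 with Delta and at 13.17 on both Notch intra arrays. With COX7a RNAi it stood at 10.50 and 10.54, and with Delta and COX7a RNAi at 10.88 and 11.20. The fall was -2.85 ± 0.09 against GFP (limma adjusted p = 5.18e-06) and -2.21 ± 0.09 against Delta (adjusted p = 1.37e-05). Delta mRNA was 1.96 ± 0.15 higher in the Delta discs (adjusted p = 0.000376) and 1.81 ± 0.15 higher with Delta and COX7a RNAi (adjusted p = 0.000447). A second Delta probe set gave 0.58 and 0.45 for the same comparisons. Delta mRNA differed by 0.23 ± 0.15 in Notch intra, which did not pass the test (adjusted p = 0.372). The Notch and white genes were not analysed here, because no probe set was annotated with either gene alone. The gene tio, which some lines of the hairpin collection can misexpress, was not called against GFP with COX7a RNAi (-0.21 ± 0.12) and fell with Delta and COX7a RNAi (-0.51 ± 0.12, adjusted p = 0.0359). The tio call was lost in 5 of the 10 fits that left out an array, with an adjusted p of up to 0.219.

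**Figure D1:**
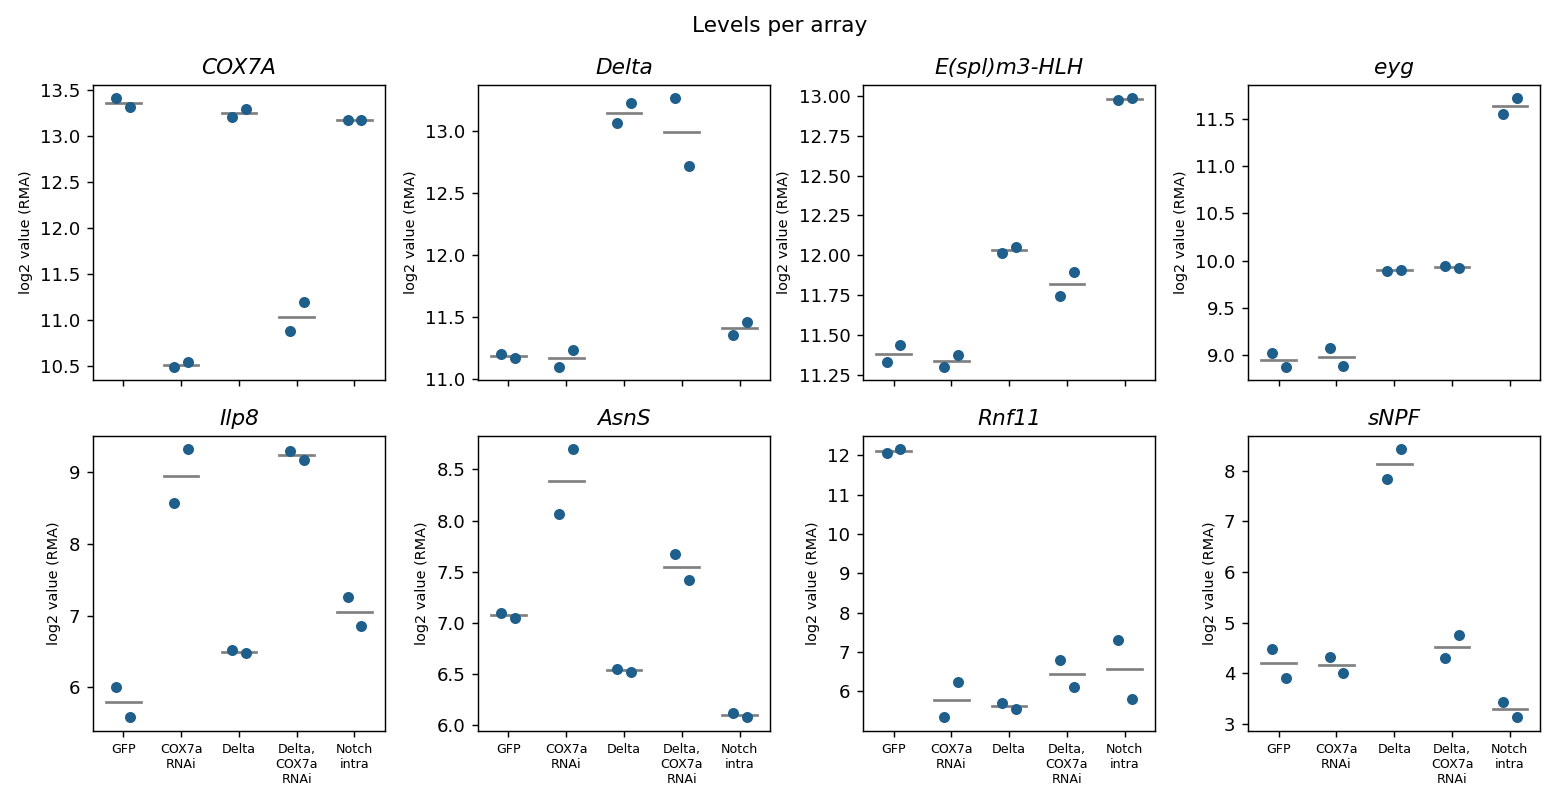
Log2 values (vertical axes, RMA) of 8 genes on each of the 10 arrays, by genotype (horizontal axis); points are arrays and grey lines the mean of the 2 arrays. COX7A was lower in both genotypes with the hairpin, Rnf11 was high in GFP alone at 12.11, and sNPF in Delta alone at 8.13.

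With COX7a RNAi alone Ilp8, a relaxin-like peptide that abnormally growing discs secrete to delay metamorphosis, rose by 3.14 ± 0.24, an 8.79-fold change. ImpL2, a secreted antagonist of insulin-like peptides, rose by 2.87 ± 0.12. The amino acid transporter gene path rose by 2.98 ± 0.12 and the trehalose transporter gene Tret1-1 by 2.76 ± 0.29. The other genes with the highest fold changes were JhI-26 (3.89 ± 0.25), Hsc70-2 (3.33 ± 0.22), CG6830 (3.21 ± 0.22) and CG11893 (3.10 ± 0.33), Akh, which encodes adipokinetic hormone (2.68 ± 0.30), and the cytochrome P450 gene Cyp6a20 (2.64 ± 0.32). Hsc70-2 and CG11893 were at or under the floor in GFP. Whether the Akh signal, here and in the comparisons below, came from disc cells or from attached tissue was not tested. The lowest fold changes were Rnf11 (-6.33 ± 0.46), COX7A (-2.85 ± 0.09), ImpE2 (-1.90 ± 0.22) and CG4250 (-1.74 ± 0.26), followed by CG32572 (-1.63 ± 0.14), which was under the floor with COX7a RNAi. Rnf11, ImpE2 and CG32572 were also called lower than GFP with Delta, with both transgenes and with Notch intra, so their falls are not specific to COX7a RNAi. In total 394 genes were called, 265 higher and 129 lower, and 59 of them changed at least 2-fold (46 higher and 13 lower).

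Among the gene lists, the cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had a mean of 0.31. Of 18 measured, 11 rose, 13 when adjusted over the list alone, with AsnRS (0.59), TrpRS (0.56) and LeuRS (0.55) ahead (camera adjusted p = 1.79e-14; adjusted p = 0.634 with an estimated correlation). In the list of the ATF4 pathway and of serine, one-carbon and asparagine synthesis, 4 of 13 rose (5 higher and 1 lower when adjusted over the list alone), led by Gadd45 (1.48), the asparagine synthetase gene AsnS (1.31) and Nmdmc (0.69), a mitochondrial enzyme gene of one-carbon metabolism (camera adjusted p = 0.0163; adjusted p = 0.634 with an estimated correlation). Glycolysis genes rose in 4 of 12 cases, 10 when adjusted over the list alone, among them Pfk (1.17), Tpi (0.95) and Pgk (0.38) (camera adjusted p = 8.14e-07; adjusted p = 0.634 with an estimated correlation). Of 10 mitochondrial chaperone and protease genes 4 rose, 5 higher and 1 lower when adjusted over the list alone, with Roe1 (0.93), Hsc70-5 (0.61) and Hsc20 (0.44) first (camera adjusted p = 0.00292; adjusted p = 0.634 with an estimated correlation). In the oxidative stress and glutathione list 6 of 28 rose, 7 higher and 1 lower when adjusted over the list alone, led by the glutathione transferase genes GstE6 (1.30), GstE5 (0.91) and GstD9 (0.88) (camera adjusted p = 0.00752; adjusted p = 0.634 with an estimated correlation). The JNK and wound list had 4 of 12 higher, 4 higher and 1 lower when adjusted over the list alone, namely Ilp8, Gadd45, scaf (0.89) and 1 further gene (camera adjusted p = 0.0289; adjusted p = 0.665 with an estimated correlation). In the apoptosis, p53 and cell competition list the caspase gene Dronc rose (0.33), 1 of 8, and 3 when adjusted over the list alone (camera adjusted p = 0.0264; adjusted p = 0.634 with an estimated correlation). Tracheal markers were lower in 2 of 5 cases, 3 when adjusted over the list alone, with serp at -0.44 and Gasp at -0.31 (camera adjusted p = 0.0138; adjusted p = 0.634 with an estimated correlation). COX7A was the 1 complex IV gene of 9 called, and of 42 other respiratory chain and ATP synthase genes none was called by limma (mean 0.04), with 7 at an unadjusted p under 0.05. Without GFP replicate 1 the total count was 127 and without GFP replicate 2 it was 158. Leaving out an array lost these calls, with the highest adjusted p in brackets. CG4250 (0.0682) and LeuRS (0.059) were lost without GFP replicate 2. Dronc (0.142) was lost without GFP replicate 1 or 2 or COX7a RNAi replicate 2. Gadd45 (0.232) was lost without any array but COX7a RNAi replicate 1 and Delta with COX7a RNAi replicate 1 or 2. Gasp (0.149) was lost without GFP replicate 1 or COX7a RNAi replicate 2. Hsc20 (0.0921) was lost without GFP replicate 1. Pfk (0.0631) and Tpi (0.0931) were lost without GFP replicate 1 or 2. Pgk (0.182) was lost without any array but COX7a RNAi replicate 1 and Delta replicate 1 or 2 and Delta with COX7a RNAi replicate 1 or 2. scaf (0.152) and serp (0.21) were lost without GFP replicate 1 or 2 or COX7a RNAi replicate 1 or 2. The apoptosis list (0.21), the ATF4 list (0.0624), the JNK and wound list (0.0762) and the oxidative stress list (0.108) were lost without COX7a RNAi replicate 2. The ATF4 list mean of 0.36 was 0.22 without COX7a RNAi replicate 2. The apoptosis list mean of 0.19 was 0.12 without COX7a RNAi replicate 2.

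Of 8 measured genes of the Enhancer of split complex, the direct targets of Notch signalling, 2 rose with Delta, E(spl)m2-BFM by 1.00 ± 0.17 and E(spl)m3-HLH by 0.65 ± 0.06, and 6 were higher when adjusted over the list alone (camera adjusted p = 9.9e-06; adjusted p = 0.634 with an estimated correlation). The Notch-regulated eye growth gene eyg rose by 0.95 ± 0.08 and the transcription factor gene dpn by 0.84 ± 0.13. The highest fold changes were those of the neuropeptide gene sNPF (3.93 ± 0.26), the cuticle protein gene Cpr56F (3.48 ± 0.30), CtsL2 (3.07 ± 0.17), the neuropeptide gene AstC (2.70 ± 0.18) and the serpin gene Spn28B (2.49 ± 0.25), of which sNPF, AstC and Spn28B were at or under the floor in GFP. The lowest were Rnf11 (-6.48 ± 0.46), CG6701 (-3.34 ± 0.14), CG13056 (-2.75 ± 0.13), CR44101 (-2.43 ± 0.33) and MFS15 (-1.88 ± 0.08), bnl, which encodes an FGF ligand (-1.86 ± 0.13), and the phosphoenolpyruvate carboxykinase gene Pepck1 (-1.82 ± 0.13). CR44101 was under the floor with Delta, and the other 2 probe sets of bnl gave -0.33 and -0.64 without passing the test. The eye gene Optix fell by 0.36 ± 0.07 and the glutathione transferase gene GstE5 by 1.16 ± 0.08.

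The ribosome biogenesis list was shifted up by a mean of 0.09 (camera adjusted p = 0.0088; adjusted p = 0.682 with an estimated correlation) and the cell cycle and replication list by 0.08 (camera adjusted p = 0.0357; adjusted p = 0.767 with an estimated correlation). No single gene of either list was called by limma, over all genes or when adjusted over the list alone, and 3 of 16 and 4 of 16 had an unadjusted p under 0.05. In all, 207 genes were called, 117 higher and 90 lower, 51 of them at least 2-fold (27 higher and 24 lower). A second quantile normalization gave 104 higher and 99 lower, and centring each array on its median 132 and 79. Without 1 array, the count was 74 and 80 for the GFP replicates and 90 and 110 for the Delta replicates left out. Some calls were lost when an array was left out (highest adjusted p in brackets). CR44101 (0.0657) was lost without GFP replicate 1 or 2 or Delta replicate 1 or 2. dpn (0.092) was lost without GFP replicate 2 or Delta replicate 1 or 2. E(spl)m2-BFM (0.163) and Optix (0.187) were lost without any array but COX7a RNAi replicate 1 or 2 and Delta with COX7a RNAi replicate 1 or 2. The cell cycle list (0.126) was lost without GFP replicate 2 or Delta replicate 1. The ribosome biogenesis list (0.217) was lost without GFP replicate 2. The ribosome biogenesis list mean of 0.09 was 0.06 without GFP replicate 2.

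Notch intra changed the most genes of the comparisons with GFP. Of the 8 Enhancer of split genes 6 rose, all 8 when adjusted over the list alone, led by E(spl)m2-BFM (2.25 ± 0.17), E(spl)m3-HLH (1.59 ± 0.06) and E(spl)m4-BFM (1.42 ± 0.27; camera adjusted p = 1.95e-06; adjusted p = 0.634 with an estimated correlation). Of 9 other Notch-regulated genes 5 were higher and 1 lower, 5 and 2 when adjusted over the list alone, with eyg at 2.69 ± 0.08, dpn at 2.03 ± 0.13 and klu at 0.95 ± 0.18, in a list that did not pass (camera adjusted p = 0.0596; adjusted p = 0.634 with an estimated correlation). Antennal patterning genes fell in 6 of 11 cases, 8 when adjusted over the list alone, namely the antennal identity gene ss (-3.95 ± 0.49), the appendage gene Dll (-2.46 ± 0.27), bab2 (-1.59 ± 0.27) and 3 others (camera adjusted p = 2.73e-06; adjusted p = 0.634 with an estimated correlation). The ss value rests on a level under the floor in Notch intra, and the other Dll probe sets gave -0.94 and -2.94. The highest fold changes were Cyp4p2 (5.32 ± 0.12), Ekar (5.15 ± 0.29), Cyp4p1 (4.20 ± 0.18), Cpr56F (4.13 ± 0.30), Akh (3.75 ± 0.30) and CG14075 (3.59 ± 0.33), with Ekar at or under the floor in GFP. The lowest were Rnf11 (-5.55 ± 0.46), CG13056 (-4.28 ± 0.13), bnl (-4.04 ± 0.13), ss (-3.95 ± 0.49), Cpr78E (-3.36 ± 0.62) and CG4250 (-3.07 ± 0.26), with bnl under the floor in Notch intra and at -0.45 and -1.13 by its other probe sets.

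Muscle markers had 2 of 9 lower, 6 when adjusted over the list alone, with Act87E at -1.82 and Mp20 at -1.60 (camera adjusted p = 0.00149; adjusted p = 0.634 with an estimated correlation). Tracheal markers had 2 of 5 lower, 3 when adjusted over the list alone, with Gasp at -1.37 and serp at -1.17 (camera adjusted p = 0.00886; adjusted p = 0.634 with an estimated correlation). The glial transcription factor gene repo fell by 2.14 ± 0.23 and the glial barrier gene moody by 1.38 ± 0.18, in a neuron and glia list that did not pass (adjusted p = 0.187). The JNK and wound list had a mean of -0.22, with scaf at -1.32 and egr at -0.72 against a rise of Ilp8 (1.26), 3 of 12 lower and 1 higher, 6 and 1 when adjusted over the list alone (camera adjusted p = 0.0412; adjusted p = 0.682 with an estimated correlation). Endoplasmic reticulum chaperone genes had a mean of -0.17, with 1 of 13, the secreted factor gene Manf, lower over all genes and when adjusted over the list alone (-0.41; camera adjusted p = 0.00308; adjusted p = 0.634 with an estimated correlation). Respiratory chain and ATP synthase genes other than complex IV had a mean of -0.06, with 1 of 42, ND-15, lower over all genes and when adjusted over the list alone (-0.32; camera adjusted p = 0.0117; adjusted p = 0.902 with an estimated correlation). Cell cycle genes rose in 3 of 16 cases, also when adjusted over the list alone, with the helicase genes Mcm2 (0.28) and Mcm5 (0.21) and the kinase gene aurB (0.18; camera adjusted p = 0.0358; adjusted p = 0.767 with an estimated correlation). Ribosome biogenesis genes rose in 4 of 16 cases, 7 when adjusted over the list alone, among them Ns1 (0.25) and Fib (0.24; camera adjusted p = 0.0163; adjusted p = 0.757 with an estimated correlation). Photoreceptor genes svp (-2.08 ± 0.34) and sens (-1.60 ± 0.37) fell, in a list that did not pass (adjusted p = 0.0538).

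Notch intra called 1144 genes against GFP, 525 higher and 619 lower, 246 of them at least 2-fold (74 higher and 172 lower). With a second quantile normalization 539 were higher and 591 lower, and with arrays centred on their median 394 and 645. The count was 545 and 555 without GFP replicates 1 and 2, and 578 and 592 without Notch intra replicates 1 and 2. Calls lost without an array are given with their highest adjusted p. aurB (0.201) was lost without any array but COX7a RNAi replicate 1 or 2 and Delta with COX7a RNAi replicate 1 or 2. bab2 (0.0557) was lost without Notch intra replicate 2. Cpr78E (0.0697) was lost without GFP replicate 1 or Notch intra replicate 2. E(spl)m4-BFM (0.071) was lost without GFP replicate 1 or Notch intra replicate 1 or 2. egr (0.217) was lost without any array but COX7a RNAi replicate 1 or 2 and Delta with COX7a RNAi replicate 1 or 2 and Notch intra replicate 1. Fib (0.069) was lost without GFP replicate 2 or Notch intra replicate 2. Ilp8 (0.0902), klu (0.0746), Manf (0.0563), Ns1 (0.111) and the cell cycle list (0.173) were lost without GFP replicate 2 or Notch intra replicate 1. Mcm5 (0.114) and sens (0.141) were lost without GFP replicate 1 or 2 or Notch intra replicate 1 or 2. ND-15 (0.0565) was lost without GFP replicate 1 or 2 or Notch intra replicate 1. The JNK and wound list (0.149) was lost without GFP replicate 1 or COX7a RNAi replicate 2 or Notch intra replicate 2. The respiratory chain and ATP synthase list (0.184) was lost without GFP replicate 1 or Notch intra replicate 1. The ribosome biogenesis list (0.124) was lost without GFP replicate 2. The respiratory chain and ATP synthase list mean of -0.06 was -0.04 without Notch intra replicate 1.

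Delta and Notch intra shared many calls against GFP. Among the shared genes were E(spl)m3-HLH, eyg and dpn on the higher side and Rnf11, CG13056, bnl and Optix on the lower side. In all, 70 genes were higher in both, where independent lists would share 7.06, and 69 were lower in both, where independent lists would share 6.4. Of the 139 shared calls, 46 (23 higher and 23 lower, among them Rnf11 and CG13056) were made in the same direction also with COX7a RNAi alone and with both transgenes. These calls were thus not confined to genotypes with Delta or Notch intra, but the sizes could differ. Rnf11 fell about as far with COX7a RNAi as with Delta. CG13056 stood at 10.45 log2 units in GFP, 9.83 with COX7a RNAi, 7.69 with Delta and 6.16 with Notch intra. Only 4 genes were called in opposite directions. Because both comparisons use the same GFP arrays, chance alone gives some overlap. In 100 simulations without any effect the shared calls averaged 0.01 and reached at most 1, where the adjusted cutoff admits almost no genes. In 100 more, added after the result was seen and held to the unadjusted p cutoffs of the real fits, they averaged 3.74 and reached at most 9. The covariance of the log2 fold changes across genes was 0.0442, against a simulated 0.00859 from the shared arrays, a difference of 0.0357. Their Pearson correlation across genes was 0.450, not above the 0.499 that the shared arrays gave in the simulations. Part of the excess over independent lists may still come from the shared controls, since 2 control arrays are too few to give each comparison its own pair. Together the 139 shared calls fell to 51 and 53 without GFP replicates 1 and 2, to 66 and 67 without Delta replicates 1 and 2, and to 88 and 83 without Notch intra replicates 1 and 2.

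**Figure D2:**
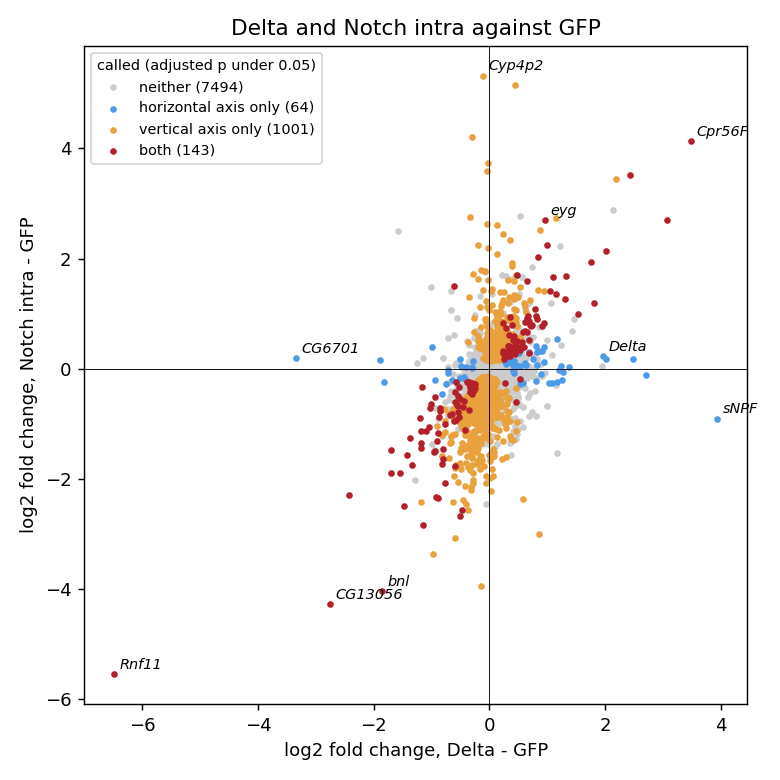
Log2 fold change against GFP of each of 8702 tested genes with Delta (horizontal axis) and with Notch intra (vertical axis); colours show in which comparison a gene was called. Rnf11, CG13056 and bnl fell in both, and Cpr56F and eyg rose in both.

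Set directly against Delta, Notch intra gave higher levels of some Notch targets. E(spl)m2-BFM was 1.25 ± 0.17 higher, E(spl)m3-HLH 0.94 ± 0.06 higher and E(spl)mbeta-HLH 0.61 ± 0.15 higher, 3 of 8 in the complex and 4 when adjusted over the list alone (camera adjusted p = 0.000435; adjusted p = 0.634 with an estimated correlation). In the list of other Notch-regulated genes, eyg (1.74 ± 0.08), dpn (1.19 ± 0.13) and klu (0.81 ± 0.18) were the 3 of 9 called, 5 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0412; adjusted p = 0.634 with an estimated correlation). Delta mRNA itself was 1.74 ± 0.15 lower than in the discs that overexpress Delta. Against GFP it differed by 0.23 in Notch intra and was not called. The Notch modifier gene fng was 0.57 ± 0.08 lower than with Delta. The eye genes toy (0.56 ± 0.05) and tsh (0.54 ± 0.06) were higher. The highest fold changes were Cyp4p2 (5.44 ± 0.12), Ekar (4.71 ± 0.29), Cyp4p1 (4.51 ± 0.18), Akh (3.77 ± 0.30) and CG14075 (3.64 ± 0.33). The lowest were sNPF (-4.84 ± 0.26), Ama (-3.85 ± 0.58), ss (-3.81 ± 0.49), Cpr49Ac (-2.95 ± 0.15) and AstC (-2.81 ± 0.18), with sNPF, ss and AstC under the floor in Notch intra.

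Antennal genes were lower in Notch intra than in Delta in 7 of 11 cases, 8 when adjusted over the list alone, with Dll at -2.06 and bab2 at -1.66 after ss (camera adjusted p = 2.73e-06; adjusted p = 0.634 with an estimated correlation). Muscle markers were lower in 2 of 9 cases, 7 when adjusted over the list alone, with Act87E at -1.66 (camera adjusted p = 0.000716; adjusted p = 0.634 with an estimated correlation), and tracheal markers in 2 of 5, 3 when adjusted over the list alone, with Gasp at -1.17 (camera adjusted p = 0.0216; adjusted p = 0.634 with an estimated correlation). The photoreceptor genes svp (-2.03), sens (-1.90) and futsch (-0.72) were lower, 3 of 15 over all genes and when adjusted over the list alone (camera adjusted p = 0.00255; adjusted p = 0.792 with an estimated correlation), although the other futsch probe sets gave 0.21 and 0.05. Respiratory genes outside complex IV had 3 of 42 lower over all genes and when adjusted over the list alone, ox (-0.30), ND-15 (-0.29) and ND-B14.7 (-0.26; camera adjusted p = 4.68e-05; adjusted p = 0.767 with an estimated correlation). Endoplasmic reticulum genes had 2 of 13 lower in both counts, Cnx99A (-0.37) and Manf (-0.31; camera adjusted p = 0.00724; adjusted p = 0.639 with an estimated correlation). Glutathione transferase genes led 6 higher of 28 in the oxidative stress list, 9 higher and 1 lower when adjusted over the list alone, with GstD6 at 1.95, GstD5 at 1.08 and GstE5 at 0.83 (camera adjusted p = 0.0038; adjusted p = 0.634 with an estimated correlation). GstD6 and GstD5 were under the floor in Delta. The comparison called 831 genes, 283 higher and 548 lower, a share of higher calls of 34.1% that was 44.4% after a second quantile normalization and 22.2% after centring each array on its median. The count was 311 and 499 without Delta replicates 1 and 2, and 389 and 348 without Notch intra replicates 1 and 2. Leaving out an array lost these calls, with the highest adjusted p in brackets. bab2 (0.0628) and svp (0.0678) were lost without Delta replicate 1 or Notch intra replicate 2. Cnx99A (0.178) was lost without any array but COX7a RNAi replicate 1 or 2 and Delta replicate 2 and Delta with COX7a RNAi replicate 1 or 2. E(spl)mbeta-HLH (0.217) and ox (0.169) were lost without any array but COX7a RNAi replicate 1 or 2 and Delta with COX7a RNAi replicate 1 or 2. futsch (0.165), klu (0.149) and ND-B14.7 (0.153) were lost without Delta replicate 1 or 2 or Notch intra replicate 1 or 2. Manf (0.17) was lost without any array but COX7a RNAi replicate 1 or 2 and Delta with COX7a RNAi replicate 1 or 2 and Notch intra replicate 2. ND-15 (0.102) was lost without Delta replicate 2 or Notch intra replicate 1 or 2. sens (0.11) was lost without Delta replicate 1 or 2 or Notch intra replicate 2. The other Notch-regulated gene list (0.0856) was lost without Delta replicate 2 or Delta with COX7a RNAi replicate 1 or 2 or Notch intra replicate 1. The tracheal marker list (0.0511) was lost without Notch intra replicate 1. The other Notch-regulated gene list mean of 0.17 was 0.09 without Notch intra replicate 1. The muscle markers list mean of -1.22 was -0.71 without Delta replicate 1.

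**Figure D3:**
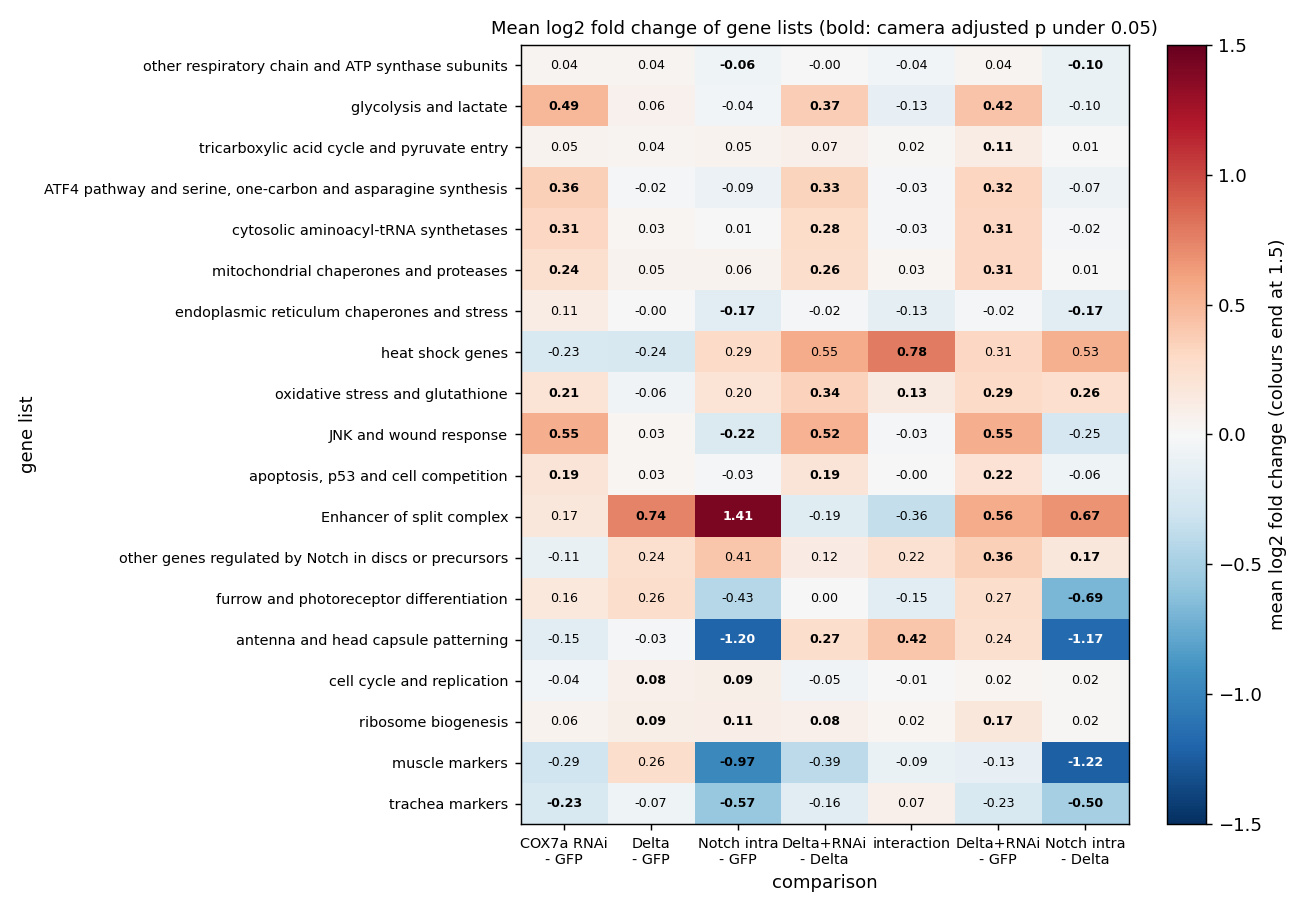
Mean log2 fold change of the 19 gene lists (rows) called in at least 1 comparison, for the 7 comparisons (columns); colour and printed value give the mean and bold marks a camera adjusted p under 0.05. The Enhancer of split complex had its highest mean in Notch intra against GFP (1.41), and the aminoacyl-tRNA synthetases were shifted up by 0.31 and 0.28 with COX7a RNAi in the GFP and Delta backgrounds. None of the 52 list calls passed by camera with an estimated correlation, and 19 of them were kept by fry.

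In the Delta background, 115 of the 190 genes called higher with COX7a RNAi were also called higher with it alone. Ilp8 rose by 2.72 ± 0.24 and ImpL2 by 3.44 ± 0.12. The other genes with the highest fold changes were Hsc70-2 (4.10 ± 0.22), JhI-26 (3.58 ± 0.25), CG11893 (3.11 ± 0.33), CG6830 (2.96 ± 0.22) and Pepck1 (2.94 ± 0.13), with Hsc70-2 and CG11893 at or under the floor in Delta. The lowest were sNPF (-3.61 ± 0.26), Spn28B (-2.57 ± 0.25), CtsL2 (-2.52 ± 0.17), AstC (-2.50 ± 0.18) and CG4250 (-2.24 ± 0.26) and COX7A, and sNPF, Spn28B and AstC, which Delta alone had raised, were at or under the floor with both transgenes. The FGF gene bnl was 0.92 ± 0.13 higher, a call its other probe sets (0.13 and 0.29) did not share.

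Of 18 aminoacyl-tRNA synthetase genes 11 rose, 12 when adjusted over the list alone, with AsnRS (0.59), ValRS (0.54) and LeuRS (0.49) ahead (camera adjusted p = 2.57e-14; adjusted p = 0.634 with an estimated correlation). Glycolysis genes rose in 2 of 12 cases, 7 when adjusted over the list alone, Pfk (0.92) and Eno (0.25; camera adjusted p = 7.35e-06; adjusted p = 0.634 with an estimated correlation). The ATF4 list had 3 of 13 higher, 5 when adjusted over the list alone, Gadd45 (1.55), AsnS (1.01) and Nmdmc (0.47; camera adjusted p = 0.000505; adjusted p = 0.634 with an estimated correlation). Mitochondrial chaperone genes rose in 3 of 10 cases, 6 when adjusted over the list alone, Roe1 (0.73), Hsc20 (0.34) and Hsp60A (0.19; camera adjusted p = 8.57e-06; adjusted p = 0.634 with an estimated correlation). Oxidative stress genes rose in 6 of 28 cases, 9 when adjusted over the list alone, led by GstE5 (2.27), GstE6 (1.72) and GstE7 (1.02; camera adjusted p = 9.9e-06; adjusted p = 0.634 with an estimated correlation). The JNK and wound list had 3 of 12 higher, 6 when adjusted over the list alone, Ilp8, Gadd45 and scaf (1.04; camera adjusted p = 0.000764; adjusted p = 0.634 with an estimated correlation). Irbp (0.40) was the 1 gene of 8 called in the apoptosis list, where 4 were higher when adjusted over the list alone (camera adjusted p = 0.0206; adjusted p = 0.634 with an estimated correlation). Ribosome biogenesis genes were shifted by a mean of 0.08, 3 of 16 higher when adjusted over the list alone and none over all genes in limma, where 4 had an unadjusted p under 0.05 (camera adjusted p = 0.000762; adjusted p = 0.634 with an estimated correlation). Antennal genes were shifted by a mean of 0.27 with no gene called in either way and 1 of 11 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.0196; adjusted p = 0.767 with an estimated correlation). In total 326 genes were called, 190 higher and 136 lower, 57 of them at least 2-fold (41 higher and 16 lower). The count was 104 and 136 without Delta replicates 1 and 2, 204 and 203 without GFP replicates 1 and 2, and 217 without either Notch intra replicate. Leaving out an array lost these calls, with the highest adjusted p in brackets. AsnS (0.122) was lost without Delta replicate 1 or 2 or Delta with COX7a RNAi replicate 1. bnl (0.0604) was lost without Delta replicate 1. Eno (0.177), Gadd45 (0.219), Hsp60A (0.208) and Irbp (0.198) were lost without any array but COX7a RNAi replicate 1 or 2 and Delta with COX7a RNAi replicate 2. Hsc20 (0.177) and Pfk (0.155) were lost without any array but COX7a RNAi replicate 1 or 2. LeuRS (0.093) was lost without Delta replicate 2 or Delta with COX7a RNAi replicate 1. Nmdmc (0.0962) was lost without Delta replicate 2 or Delta with COX7a RNAi replicate 1 or 2. scaf (0.0939) was lost without Delta replicate 1 or 2. The antenna list (0.105) was lost without Delta replicate 2 or Delta with COX7a RNAi replicate 2. The apoptosis list (0.187) was lost without Delta replicate 1 or Delta with COX7a RNAi replicate 1. The glycolysis list mean of 0.37 was 0.23 without Delta replicate 2. The apoptosis list mean of 0.19 was 0.11 without Delta with COX7a RNAi replicate 1. The antenna list mean of 0.27 was 0.17 without Delta with COX7a RNAi replicate 2.

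The COX7a RNAi calls of the GFP and Delta backgrounds overlapped. Ilp8, ImpL2, JhI-26, Hsc70-2, AsnS and AsnRS were higher and COX7A and CG4250 lower in both. In all 115 genes were higher in both (5.79 for independent lists; Fisher's exact test, two-sided p = 5.65e-134) and 20 were lower in both (2.02 for independent lists; two-sided p = 6.2e-15), while 3 went opposite ways. These comparisons use different arrays and share the estimate of the spread. Replicate differences of the 2 hairpin genotypes correlated at 0.38 across genes, so a factor shared by their arrays cannot be excluded. Across genes, which are not independent replicates, the fold changes correlated at Pearson's r = 0.449 and Spearman's rho = 0.295. The 135 shared calls fell to 75 and 76 without GFP replicates 1 and 2, and to 65 and 59 without Delta replicates 1 and 2.

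**Figure D4:**
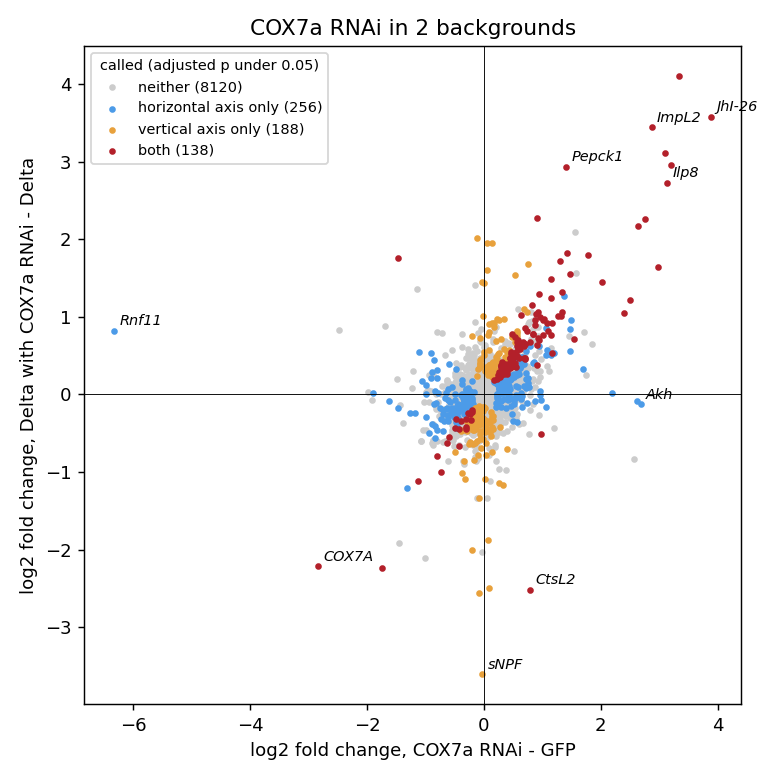
Log2 fold change of each of 8702 tested genes with COX7a RNAi against GFP (horizontal axis) and in the Delta background against Delta (vertical axis); colours show in which comparison a gene was called. JhI-26, Ilp8 and ImpL2 rose in both, whereas sNPF fell by 3.61 in the Delta background alone.

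A test of the interaction asked whether COX7a RNAi had a different effect in the Delta background than in the GFP background. Pepck1 had a larger rise with Delta (interaction 1.53 ± 0.19), as did the glutathione transferase gene GstE5 (1.36 ± 0.12). Both rose from a lower level in Delta than in GFP, for Pepck1 9.12 against 10.94 and for GstE5 6.18 against 7.34. The levels reached were close, for Pepck1 12.34 with COX7a RNAi alone and 12.06 with both transgenes, and for GstE5 8.25 and 8.45. The neuropeptide genes sNPF (-3.57 ± 0.37), Akh (-2.81 ± 0.42) and AstC (-2.58 ± 0.25) and the genes CtsL2 (-3.31 ± 0.24) and Spn28B (-2.49 ± 0.35) had lower values with COX7a RNAi in the Delta background than the separate effects would add up to. The highest interaction values were those of Rnf11 (7.15 ± 0.66), CG6701 (3.22 ± 0.20), spz4 (2.13 ± 0.24), ImpE2 (1.92 ± 0.31) and Est-Q (1.90 ± 0.26). Of these, sNPF, AstC and Spn28B were at or under the floor with GFP, COX7a RNAi and both transgenes, and Est-Q with GFP, COX7a RNAi and Delta. Rnf11 and ImpE2 were higher in GFP than in every other genotype, for Rnf11 at 12.11 against 5.63 to 6.56. Their interaction values cannot be told apart from a difference of the GFP arrays. In all 50 genes were called, 23 with a positive and 27 with a negative interaction. The COX7A interaction of 0.63 ± 0.13 did not pass (adjusted p = 0.0878). Of 18 aminoacyl-tRNA synthetase genes none had a called interaction in limma (mean -0.03; 1 at an unadjusted p under 0.05), and of 12 glycolysis genes none did (mean -0.13; 0 at an unadjusted p under 0.05). The count was 16 and 27 without GFP replicates 1 and 2, 24 and 32 without Delta replicates 1 and 2, and 32 without replicate 1 of Delta with COX7a RNAi. Some calls were lost when an array was left out (highest adjusted p in brackets). Akh (0.132) was lost without any array but COX7a RNAi replicate 2 and Notch intra replicate 1 or 2. Est-Q (0.0951) was lost without any array but Delta replicate 1 and Delta with COX7a RNAi replicate 2 and Notch intra replicate 1 or 2. ImpE2 (0.188) was lost without any array but COX7a RNAi replicate 1 or 2. Pepck1 (0.0565) was lost without Delta replicate 2 or Delta with COX7a RNAi replicate 1. Spn28B (0.12) was lost without any array but Delta replicate 1 and Notch intra replicate 1 or 2. spz4 (0.0578) was lost without GFP replicate 1. The antenna list (0.212) was lost without COX7a RNAi replicate 1. The heat shock list (0.129) was lost without GFP replicate 1 or COX7a RNAi replicate 1 or Delta replicate 2 or Delta with COX7a RNAi replicate 1. The oxidative stress list (0.518) was lost without GFP replicate 1 or COX7a RNAi replicate 1 or Delta replicate 1 or Delta with COX7a RNAi replicate 1.

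Compared with GFP, discs with both Delta and COX7a RNAi carried changes seen with each transgene alone, although sNPF, AstC and Spn28B stayed at or under the floor. The Notch targets E(spl)m2-BFM (0.84 ± 0.17) and E(spl)m3-HLH (0.43 ± 0.06) rose, 2 of 8, and 3 when adjusted over the list alone (camera adjusted p = 0.0027; adjusted p = 0.682 with an estimated correlation), as did eyg (0.98 ± 0.08), dpn (0.86 ± 0.13) and the JAK/STAT ligand gene upd1 (0.44 ± 0.10), 3 of the 9 other Notch-regulated genes and 4 when adjusted over the list alone (camera adjusted p = 0.0491; adjusted p = 0.634 with an estimated correlation). Ilp8 rose by 3.43 ± 0.24 and ImpL2 by 2.86 ± 0.12, next to Hsc70-2 (3.90 ± 0.22), JhI-26 (3.55 ± 0.25) and CG11893 (3.47 ± 0.33), of which Hsc70-2 and CG11893 were under the floor in GFP. The lowest fold changes were Rnf11 (-5.67 ± 0.46), CG13056 (-3.04 ± 0.13), CG4250 (-2.83 ± 0.26), CR44101 (-2.48 ± 0.33) and COX7A (-2.33 ± 0.09), with CR44101 under the floor in the discs with both. The eye genes Optix (-0.51 ± 0.07) and so (-0.34 ± 0.05) fell.

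Of 18 aminoacyl-tRNA synthetase genes 11 rose, 16 when adjusted over the list alone (camera adjusted p = 5.18e-12; adjusted p = 0.634 with an estimated correlation), and of 16 ribosome biogenesis genes 6 rose, 14 when adjusted over the list alone, led by ppan (0.26; camera adjusted p = 8.14e-07; adjusted p = 0.634 with an estimated correlation). Glycolysis had 3 of 12 higher, 8 when adjusted over the list alone, with Pfk at 0.92 (camera adjusted p = 7.74e-05; adjusted p = 0.634 with an estimated correlation). The tricarboxylic acid cycle list had a mean of 0.11, 3 of 12 higher when adjusted over the list alone and none over all genes in limma, where 5 had an unadjusted p under 0.05 (camera adjusted p = 0.0453; adjusted p = 0.634 with an estimated correlation). The ATF4 list had 2 of 13 higher, 3 when adjusted over the list alone, Gadd45 (1.36) and Nmdmc (0.76; camera adjusted p = 0.0174; adjusted p = 0.634 with an estimated correlation). Mitochondrial chaperone genes had 5 of 10 higher, 6 when adjusted over the list alone, led by Roe1 (1.09; camera adjusted p = 0.000303; adjusted p = 0.634 with an estimated correlation). The oxidative stress list had 8 of 28 higher and 1 lower, 9 and 1 when adjusted over the list alone, led by GstE6 (1.57; camera adjusted p = 0.00386; adjusted p = 0.634 with an estimated correlation). The JNK and wound list had 5 of 12 higher, 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0212; adjusted p = 0.634 with an estimated correlation). The apoptosis list had 1 of 8 higher, Irbp (0.42), and 4 when adjusted over the list alone (camera adjusted p = 0.0256; adjusted p = 0.634 with an estimated correlation). Altogether 658 genes were called, 401 higher and 257 lower, 79 of them at least 2-fold (55 higher and 24 lower). The split was 350 and 301 after a second quantile normalization, and 444 and 209 after centring each array on its median. The count was 265 and 206 without GFP replicates 1 and 2, and 390 without replicate 2 of Delta with COX7a RNAi. Calls lost without an array are given with their highest adjusted p. E(spl)m2-BFM (0.176) and ppan (0.153) were lost without GFP replicate 1 or 2 or Delta with COX7a RNAi replicate 2. Gadd45 (0.248) was lost without any array but COX7a RNAi replicate 1 or 2 and Delta with COX7a RNAi replicate 2. Irbp (0.179) and Pfk (0.115) were lost without GFP replicate 1 or 2 or Delta with COX7a RNAi replicate 1. upd1 (0.168) was lost without any array but COX7a RNAi replicate 1 or 2. The apoptosis list (0.188), the ATF4 list (0.0586), the JNK and wound list (0.18) and the oxidative stress list (0.0871) were lost without Delta with COX7a RNAi replicate 1. The Enhancer of split complex list (0.102) was lost without Delta with COX7a RNAi replicate 2. The other Notch-regulated gene list (0.16) was lost without GFP replicate 1 or Delta replicate 1 or 2 or Delta with COX7a RNAi replicate 2. The tricarboxylic acid cycle list (0.109) was lost without GFP replicate 2 or Delta with COX7a RNAi replicate 1 or 2. The apoptosis list mean of 0.22 was 0.14 without Delta with COX7a RNAi replicate 1. The Enhancer of split list mean of 0.56 was 0.87 without Delta with COX7a RNAi replicate 1 and 0.24 without Delta with COX7a RNAi replicate 2.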

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

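The difference between the backgrounds was tested with the interaction term. The 2 counts by effect size in the Delta background, the tests of COX7A and of Notch intra and the tests of nervous tissue genes were chosen after the results were seen. An interaction of COX7a RNAi with the background was called for 50 genes. Among the 21 named, positive differences (a higher value in the Delta background) were found for Rnf11 (7.15), CG6701 (3.22), spz4 (2.13), ImpE2 (1.92), Est-Q (1.90), MFS15 (1.81), CG6293 (1.66), CG31826 (1.56), CG32572 (1.54), Pepck1 (1.53) and GstE5 (1.36). Negative differences were found for sNPF (-3.57), CtsL2 (-3.31), Akh (-2.81), AstC (-2.58), Spn28B (-2.49), CG32373 (-2.17), tej (-1.80), Syngr (-1.49), tut (-1.48) and CG7231 (-1.41). Of these, 10 kept their call in each of the 10 fits without an array. Est-Q and CG31826 were at or under the floor in all groups but the discs with both transgenes, and sNPF, AstC and Spn28B in all 4 of the interaction's groups but Delta, CG32572 in all but GFP, and tut in GFP. A further 3 lists differed between the backgrounds, where GstE5 was the 1 gene called: heat shock genes with a mean difference of 0.78 over 5 genes (camera adjusted p = 0.0266; adjusted p = 0.634 with an estimated correlation), the antenna list with 0.42 over 11 genes, ems higher (0.56) when adjusted over the list alone (camera adjusted p = 0.00122; adjusted p = 0.634 with an estimated correlation), and oxidative stress genes with 0.13 over 28 genes (camera adjusted p = 0.0211; adjusted p = 0.671 with an estimated correlation). Without an array these list calls were lost with the highest adjusted p of 0.129 for heat shock (GFP replicate 1, COX7a RNAi replicate 1, Delta replicate 2 or Delta with COX7a RNAi replicate 1), 0.212 for antenna (COX7a RNAi replicate 1) and 0.518 for oxidative stress (GFP, COX7a RNAi, Delta or Delta with COX7a RNAi replicate 1). The oxidative stress list mean of 0.13 was 0.06 without Delta with COX7a RNAi replicate 1 and 0.21 without Delta with COX7a RNAi replicate 2. The antenna list mean of 0.42 was 0.05 without COX7a RNAi replicate 1 and 0.79 without COX7a RNAi replicate 2. In 32 of the 50 genes, a single genotype stood apart from the other 3 of the interaction by at least 2 times their range, with GFP apart in 13, Delta in 10, Delta with COX7a RNAi in 5 and COX7a RNAi in 4. Of the 21 named, Rnf11, ImpE2, CG32373, CG32572, CG6293 and tut were also called in the same direction against GFP in all 4 other genotypes. Their interaction values cannot be separated from a difference of the GFP arrays.

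COX7a RNAi acting less strongly beside a second UAS transgene is argued against for the 31 genes whose effect in the Delta background was no smaller, or opposite by over 2 standard errors, and only 7 of the 50 (3 of the 37 where GFP was not apart) had the same sign and a smaller size. For 12 more with GFP apart it is argued against as a set by Notch intra, which has no hairpin and showed a median of 0.895 (standard error 0.18) of their change from GFP with COX7a RNAi (0.971 and 0.904 with a different GFP array in each change), but not for CG3253 (-0.23) and Sulf1 (0.37), nearer GFP. It stays open for these 2 and the other 7, since COX7A had a smaller fall beside Delta (-2.21 against -2.85), although this interaction of 0.63 ± 0.13 did not pass (limma adjusted p = 0.0878). Nervous tissue attached to the Delta discs stays open for sNPF and AstC. The 9 measured neuron and glia markers had a median fold change of 0.0453 with members at the floor or moving both ways. A wider set of 26 synaptic and neurosecretory genes had a median of 0.073 and ran from -0.68 to 1.07, the highest being Syngr. Variants carried in blocks of neighbouring genes by the stocks stay open: 6 interaction genes had another within 5 tested genes on the chromosome, against a mean of 2.76 in 10000 random sets (one-sided permutation test, p = 0.149), so they cannot be told apart from an effect of the transgenes or a response to Delta and COX7a loss together, which was not tested.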

How the results depend on the processing

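All alternatives were planned. Of 316 called named-gene results, 316 kept their direction in every alternative and 165 also kept an adjusted p under 0.05 in each. The minimum fold change was not applied to these results, so called genes with smaller changes count as kept. Genes that a filter removed were not judged under it, and with all probe sets the one with the lowest p stood for its gene. Settings that alter only the filter or the spread cannot change a direction. Nor can leaving out an array for the highest and lowest named genes outside the interaction, whose arrays by the rule did not overlap between the groups. All 52 list calls kept their direction. Results that changed sign were not called: Delta in COX7a RNAi against GFP (0.0021 without GFP replicate 1, 0.0514 without COX7aRNAi replicate 1; leave-one-out range -0.081 to 0.0514), Delta in the Delta background (0.12 without Delta_COX7aRNAi replicate 2; range -0.42 to 0.12), the Delta interaction (0.14 without the same array; range -0.41 to 0.14) and tio in Notch intra against Delta (0.0225 without Notch_intra replicate 2; range -0.185 to 0.0225). Counts are given below in the order COX7a RNAi, Delta and Notch intra against GFP, COX7a RNAi in the Delta background, interaction, Delta with COX7a RNAi against GFP, Notch intra against Delta, then shared by COX7a RNAi in both backgrounds and by Delta and Notch intra. An ordinary linear model without eBayes gave 130, 84, 751, 126, 13, 277, 366, 51 and 57 calls; it drops the variance shrinkage, the trend and the added degrees of freedom together, and these were not separated. A minimum fold change of 1.5 removed smaller changes by construction and left 157, 116, 488, 124, 40, 204, 388, 61 and 70, of which the interaction count stayed within 1.5 times. Fits on the compared groups alone moved COX7a RNAi to 187, Delta to 366, COX7a RNAi in the Delta background to 118, Delta with COX7a RNAi to 328 and the shared counts to 50 and 223, and array weights moved Delta to 433, Notch intra to 1831 and its genes shared with Delta to 263; the cause was not tested. Leaving out 1 array, where the lone array of a genotype is assumed to vary like the others, gave ranges of 127 to 443, 74 to 245, 545 to 1250, 104 to 371, 16 to 42, 206 to 772, 311 to 979, 59 to 152 and 51 to 164. List calls, 52 in all, ranged from 48 to 64 without 1 array, and were 29 with fry and 0 with an estimated correlation. The replicate number as a block gave 336, 192, 1140, 322, 35, 667, 854, 123 and 130 genes and 57 lists. Replicate differences correlated between genotypes at -0.22 to 0.38, so the numbers show no pairing common to all genotypes. The highest value was that of COX7a RNAi with Delta and COX7a RNAi, where a shared factor cannot be excluded. The other settings (both filters, no trend, robust eBayes, both scalings and both uses of several probe sets) kept every count within 1.5 times. Signal over background limits genes whose group mean is at or under the floor of 4.66 log2 units.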

Other observations

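The tests of a left-out GFP array, of the unadjusted cutoffs, of attached tissue and of the antennal part were chosen after the results were seen. Beyond the comparisons above, 46 genes were called in the same direction against GFP in all 4 of the other genotypes, 23 higher and 23 lower. Rnf11, a RING finger gene, stood at 12.11 log2 units in GFP and at 5.63 to 6.56 in the others, and its second probe set fell by at least 4.53 on the log2 scale in each. ImpE2 stood at 7.93 in GFP and 6.03 to 6.41 elsewhere, and CG32373 at 6.42 in GFP and 8.61 to 9.93 elsewhere. Of the others, picked after their values were seen, bib, a channel-family gene that modifies neural fate, stood at 9.68 in GFP and 10.43 to 11.35 elsewhere, and the RNA-binding protein gene Hrb87F at 12.36 and 12.88 to 13.03.

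Chance values of single GFP arrays are argued against as the source of most of the 26 genes called in all 4 comparisons without 1 GFP array, taken as a set. In these the array left out differed from the other genotypes by a median of 0.825 (standard error 0.08) of the difference of the other GFP array, and 24 lay on the same side. The other genotypes entered as 1 mean, so the call with COX7a RNAi was not tested by itself. Of the 26, 21 were among the 46, a choice that also used the array left out, so the 21 alone are not tested. Those not among the 46 had low ratios: CG3323 (0.41), pncr008:3L (0.29), CG10898 (0.25), RanGAP (-0.08) and spok (-0.11). Simulations without an effect in any genotype gave at most 0 such genes, where the adjusted cutoff admits almost none. At the unadjusted cutoffs of the real fits they gave a mean of 0.73 and at most 3. For the 46 as a set, these argue against chance with no real change in any genotype. They left out the real changes with Delta and Notch intra, beside which a chance GFP value need only add the COX7a RNAi call. How many of the 46 hold such a chance call, and which, is not known. Variants carried by the GFP stock in blocks of neighbouring genes stay open: 6 of the 46 had another within 5 tested genes, against a mean of 2.20 in 10000 random sets (one-sided permutation test, p = 0.0873). An effect common to the transgenes other than GFP alone cannot be told apart from such variants, because GFP is the 1 control genotype.

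In Notch intra, 2 of 9 muscle markers, 2 of 5 tracheal markers and 6 of 11 antennal genes were called lower, with the glial genes repo (-2.14) and moody (-1.38); none of these 3 list calls was kept by camera with an estimated correlation (adjusted p = 0.634 for muscle, 0.634 for trachea and 0.634 for antenna). Less attached tissue of every kind stays open. The 12 hemocyte, fat body, gut and salivary gland markers at least 1 log2 unit above the floor in GFP were taken. Their median fold change was -0.0338 (standard error 0.12), against -1.10 for the 9 muscle markers. Several, such as Pxn (5.67), LManII (5.89) and Eig71Ee (5.93), lay so near the floor in GFP that a fall could hardly show, so the median cannot decide. Those with the highest GFP levels, the hemocyte markers crq (9.52), vkg (7.49) and Col4a1 (6.90), changed by -0.15, -0.01 and -0.20. In them no fall as large as the muscle median was seen. The 12 markers leave out neuron and glia markers, and less muscle, trachea and glia was not tested and stays open. A smaller antennal part of the disc could lower antennal genes, but Dll fell 1.49 log2 units less than ss, whose level in Notch intra is under the floor, and the other Dll probe sets gave -0.94 and -2.94, so this value excludes nothing. An effect of active Notch, the biological difference that the design names, was not tested here and cannot be told apart from a smaller antennal part.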
